A study of Homo sapiens with 18 samples.

How the data were processed

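RNA of OCI-AML3 cells carrying a knockout (KO) of FBXO11, of RREB1 or a control labelled safe was sequenced without treatment and after 48 hours with 25 ng/mL IFN-gamma. Per the labels' protocols, cells were grown in RPMI-1640 with 10% serum, RNA was extracted with an RNeasy kit, and libraries were made with the QuantSeq 3' mRNA kit. Per the submitters' processing notes, reads were prepared with bcl2fastq, aligned to hg19 with HISAT2, counted per gene with HTSeq and tested with DESeq2. The versions, the annotation release and the strand setting are not given in the sources used here. The deposited table holds raw counts per Ensembl gene for 18 libraries, 3 in each of 6 groups. Its values were checked to be whole numbers without normalization, and each gene in it has a total of at least 2 counts, found in at least 2 libraries. The labels number the replicates 1 to 3 and do not say whether they are separate cultures, so p values measure only the spread between these samples, which may be technical.

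Gene symbols were matched by Ensembl ID from a gene name table. Of 18611 IDs, 17825 received a symbol and 786 did not, and 72 IDs that share a symbol with another are named by ID. Reads that overlap antisense genes, paralogs such as the HLA-DRB genes, or mitochondrial pseudogenes such as MTCO2P12 cannot be assigned with certainty. Library totals ran from 4644389 to 6211720 counts (mean 5082364 ± 406488). A pair of IDs without a symbol, ENSG00000272060 and ENSG00000266658, held 8.25 to 14.6% and 1.54 to 4.66% of the counts, and transcripts of the mitochondrial genome held 5.47 to 8.39%. Copies of a library were looked for by comparing the libraries of each group pairwise, and none was found (chi-square per degree of freedom 1.92 to 10.0). Libraries of different groups with the same replicate number did not resemble each other (correlations of residuals -0.059 to 0.077 over 15 pairs of groups), so replicate numbers were not used to pair libraries.

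Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 11332 tested and 7279 untested. Library sizes were scaled by TMM, and 1 quasi-likelihood model with 1 mean per group was fitted to the 18 libraries. The 11 contrasts were each KO against control without and with IFN-gamma, IFN-gamma against none in control, FBXO11 KO and RREB1 KO, the interaction of each KO with IFN-gamma, and FBXO11 KO against RREB1 KO without and with IFN-gamma. P values were adjusted by the Benjamini-Hochberg method within a contrast, and genes under 0.05 count as changed, with no minimum fold. The common biological coefficient of variation was 0.046 and the prior degrees of freedom 50.1. CPM are scaled by TMM, and log2 CPM for components and list tests use a prior count of 2. For a gene with 0 counts in a group, the fold is given as a lower bound against 3 counts over that group. For a gene with 1 to 3 counts in a group, the ratio of CPM is given with its 95% counting interval. These bounds cover counting error only, since the reads carry no molecular identifiers that this table would show.

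The 29 gene lists were written before the data were examined, as were the contrasts, the rule for naming genes and the alternatives, except those named below as added. They cover MHC class II presentation, MHC class II promoter factors, MHC class I presentation, endolysosomal antigen processing, costimulation and checkpoint ligands, IFN-gamma response, type I interferon-stimulated genes, IFN-gamma receptor signalling, the CtBP corepressor complex, SCF-FBXO11 and its substrates, cell cycle, MYC and ribosome biogenesis, p53 targets, integrated stress and unfolded protein response, immediate early and heat shock, RAS-MAPK output, TGF-beta response, inflammatory cytokines and NF-kB, oxidative phosphorylation, cholesterol synthesis, mitochondrially encoded transcripts, the leukaemia stem and HOX programme, and markers of monocytes, granulocytes, dendritic cells, B cells, T and NK cells, erythroid and megakaryocyte cells, and epithelial and stromal cells. Each list with at least 3 tested members (26 lists) was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Members called over all genes were counted, and again with p values adjusted over the list alone. Of 15 MHC class II genes written, 11 were in the table and 9 tested. HLA-DRB5, HLA-DQA2, HLA-DQB2 and HLA-DOA had no entry, and HLA-DQA1 and HLA-DMB had too few counts.

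Genes were named by a fixed rule. It takes FBXO11 and RREB1; the measured MHC class II genes; in each KO or IFN-gamma comparison the 5 higher and 5 lower genes with the largest change among those called, with a mean of at least 5 CPM and no overlap between groups; up to 4 called members with the largest change from each list that was called or had at least 3 called members; and the 5 genes with the smallest adjusted p in interactions and between KOs. Where the text picks among these, it takes genes whose call held in each alternative that tested them, or says which alternatives ended it.

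Alternatives changed 1 choice at a time. They were DESeq2 1.42.0 (Wald test), RLE size factors, no count filter, a filter of at least 5 CPM in at least 3 libraries, a fit of only the groups compared, a replicate block, leaving out each library, and for lists an estimated correlation or a block. After the data were seen, a fit without the 2 most abundant IDs that lack a symbol and a fit of libraries thinned at random to 4644389 counts were added. The tests were also run on simulated data with the sizes of these libraries, 11332 genes and 200 changed. At a 2-fold change edgeR recovered 56 to 84% of changed genes over the 11 contrasts (lowest in the interactions) and at 1.5-fold 45 to 69%, with 2.70 to 10.1% false calls and the right sign in 100% of recovered genes. In simulated lists, camera called the 1 shifted list and 0 of 40 unshifted ones. The simulated genes varied independently, so this does not test false calls in lists whose members vary together. The shared genes of the KOs were compared with 50 simulations per condition in which both unchanged groups met the same controls. Each count of changed genes was set beside the counts from other splits of the same libraries.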

Results

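OCI-AML3, an established human acute myeloid leukaemia cell line, was profiled by QuantSeq, which counts reads from the 3' ends of polyadenylated transcripts. 18 libraries formed 6 groups of 3: control cells (labelled safe), FBXO11 knockout (KO) cells and RREB1 KO cells, each untreated or given 25 ng/mL IFN-gamma for 48 hours. FBXO11 is the substrate-binding subunit of an SCF ubiquitin ligase, and RREB1 is a zinc-finger transcription factor that can recruit CtBP corepressors. The comparisons address how knockout of either gene relates to expression of MHC class II, the proteins that present peptides to CD4 T cells. IFN-gamma is the cytokine that induces this pathway through the coactivator CIITA. Library totals ran from 4644389 to 6211720 counts, with the highest group mean in untreated RREB1 KO (5777319 ± 438058) and the lowest in untreated control (4762166 ± 60029). Untreated RREB1 KO libraries also detected more genes, 16600 to 16864 against 15566 to 15679 in untreated control. Of 18611 genes in the table, 11332 had enough counts to be tested. The first principal component held 33.2% of the variance and separated treated from untreated libraries, and the second held 20.3% and separated RREB1 KO from the other cells. Levels are CPM, counts scaled to the library sizes, given as mean ± SD over the 3 libraries of a group, and adjusted p values are from edgeR over all tested genes.

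**Figure D1:**
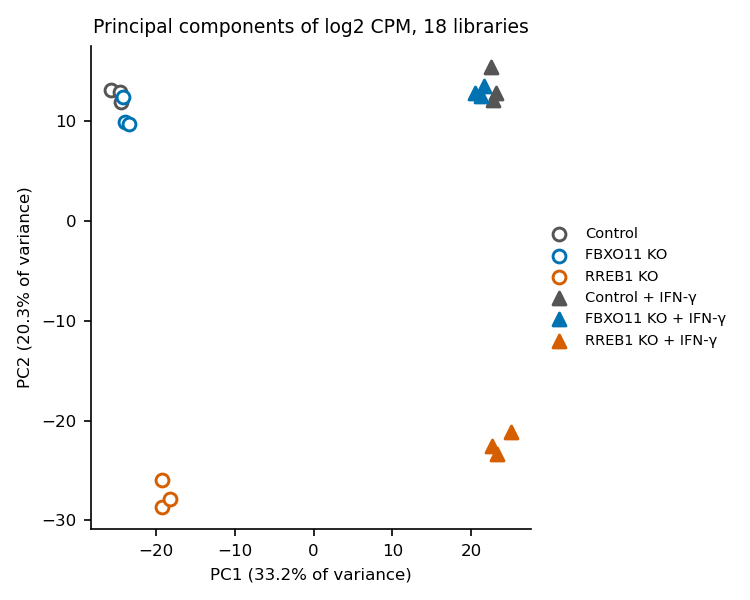
Each point is 1 of the 18 libraries, placed by the first (x axis, 33.2% of variance) and second (y axis, 20.3%) principal components of log2 CPM. Open circles are untreated and filled triangles treated libraries, and the 3 libraries of each group lie together.

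The transcripts of the targeted genes moved in opposite directions. FBXO11 (ENSG00000138081) was lower in FBXO11 KO, at 32.2 ± 1.21 against 45.5 ± 3.82 CPM in untreated control (log2 fold change -0.50 [SE 0.10], adjusted p = 8.4e-04). With IFN-gamma it was 28.8 ± 1.29 against 42.8 ± 2.18 CPM (-0.57 [SE 0.10], adjusted p = 1.0e-04). RREB1 (ENSG00000124782) was higher in RREB1 KO, at 56.3 ± 2.31 against 32.7 ± 3.49 CPM untreated (0.78 [SE 0.10], adjusted p = 1.3e-09) and 50.4 ± 2.64 against 38.6 ± 3.14 CPM with IFN-gamma (0.39 [SE 0.09], adjusted p = 0.0022). In these 4 comparisons all 3 KO libraries lay on the same side of all 3 controls. FBXO11 in RREB1 KO (-0.18 [SE 0.09] untreated, -0.15 [SE 0.10] treated) and RREB1 in FBXO11 KO (0.13 [SE 0.10] and -0.14 [SE 0.10]) did not pass the test, nor did either gene change with IFN-gamma in control, FBXO11 KO or RREB1 KO cells (adjusted p from 0.0860 to 0.852). Reads from the 3' end need not cover an edited site, so these levels do not measure loss of the protein.

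Without IFN-gamma, FBXO11 KO cells showed strong rises of genes near absent in control and modest falls of others. CKAP4, an endoplasmic reticulum membrane protein, rose from near absence to 27.0 ± 4.75 CPM, a CPM ratio to control of 373 (66.5 to 14756), where the range is the 95% counting interval. TIMP3, an inhibitor of matrix metalloproteinases, reached 23.3 ± 3.51 CPM (ratio 321 [57.3 to 12730]) and BEX3 12.6 ± 1.80 CPM (ratio 87.1 [23.8 to 725]). MS4A3, a membrane protein of granulocyte progenitors, rose by a log2 fold change of 2.95 (SE 0.31), and the unnamed gene ENSG00000271043 by 4.03 (SE 0.23). Adjusted p values of these 5 genes ran from 6.2e-28 to 1.5e-13. TMEM45A, a transmembrane protein, fell, with a log2 fold change of -1.38 (SE 0.25) (adjusted p = 7.3e-05). In total 237 genes passed in edgeR, 113 higher and 124 lower, of which 43 and 14 changed at least 2-fold. DESeq2 called 135, and a fit of only the untreated FBXO11 KO and control libraries called 373. Leaving out untreated FBXO11 KO replicate 2 or 3 gave 143 and 141, and leaving out untreated control replicate 1 gave 143.

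A few MHC class II genes rose in untreated FBXO11 KO, from low levels. HLA-DRA (ENSG00000204287), the alpha chain of HLA-DR, was 4.41 ± 1.29 against 1.02 ± 0.704 CPM (log2 fold change 2.10 [SE 0.44], adjusted p = 2.1e-04), and its beta chain partner HLA-DRB1 was 2.44 ± 1.37 against 0.436 ± 0.00142 CPM (2.39 [SE 0.65], adjusted p = 0.0045). The HLA-DRB1 call was lost without untreated FBXO11 KO replicate 1 (1.86, adjusted p = 0.122). These were the 2 called of 9 tested list members (adjusted over the list alone, 3 higher and 1 lower), and the list as a whole did not pass (adjusted p = 0.197). CD74, the chaperone that occupies the class II groove, stood at 73.0 ± 5.16 against 80.5 ± 3.67 CPM (-0.14 [SE 0.08]), and CIITA, the coactivator that switches on class II promoters, at 0.430 ± 0.234 against 0.364 ± 0.126 CPM. HLA-DMA (0.12 [SE 0.75]) and HLA-DOB (-0.70 [SE 0.30]) did not pass, HLA-DQB1 had 2 counts in each group, and HLA-DPA1 and HLA-DPB1 had 7 and 3 counts over the FBXO11 KO libraries and 0 in control.

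Genes of myeloid and stem cell identity moved in both directions in untreated FBXO11 KO. The granulocyte and promyelocyte list had 2 of 8 tested members higher and 4 lower (adjusted over the list alone, 3 and 4), and its median (-0.46) and test (down, adjusted p = 0.170) differed in sign from its mean (0.05). The neutrophil granule proteins MPO (-0.90 [SE 0.15]) and AZU1 (-0.53 [SE 0.09]) and the G-CSF receptor CSF3R (-0.71 [SE 0.10]) fell while MS4A3 rose. Of 10 leukaemia stem and HOX programme genes, 1 was higher and 2 lower (alone, 2 and 2), the falls being the transcription factors GATA2 (-0.89 [SE 0.15]) and MYB (-0.26 [SE 0.05]). Adjusted p of these 5 falls ran from 2.4e-07 to 2.1e-04. The integrated stress list was lower (adjusted p = 0.0161, and adjusted p = 0.552 with an estimated correlation), with 3 of 16 members called (alone, 6), among them asparagine synthetase ASNS (-0.37 [SE 0.07]). The 15 mitochondrially encoded transcripts were also lower as a list (adjusted p = 0.0037, and adjusted p = 0.552 with an estimated correlation), with 5 called in edgeR (alone, 11), 13 at an unadjusted p under 0.05 and 0 called in DESeq2. The ribosomal RNA MT-RNR1 fell by 0.24 on the log2 scale, a call lost in DESeq2 (adjusted p = 0.354), without untreated FBXO11 KO replicate 2 (-0.21, adjusted p = 0.0816), without untreated FBXO11 KO replicate 3 (-0.18, adjusted p = 0.145) and without untreated control replicate 1 (-0.22, adjusted p = 0.0583).

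Without IFN-gamma, RREB1 KO cells carried more MHC class II transcript than controls. HLA-DRA was 27.5 ± 2.19 against 1.02 ± 0.704 CPM (log2 fold change 4.72 [SE 0.41]) and HLA-DRB1 30.7 ± 1.91 against 0.436 ± 0.00142 CPM (6.06 [SE 0.61]). HLA-DPA1 was at least 32.3-fold and HLA-DPB1 at least 4.33-fold higher, with 127 and 17 counts over the group against 0 in control. HLA-DQB1 had a ratio of 32.1 (8.61 to 269). CD74 was 142 ± 7.76 against 80.5 ± 3.67 CPM (0.81 [SE 0.07]) and CIITA 2.78 ± 1.21 against 0.364 ± 0.126 CPM (2.83 [SE 0.78]). For the 7 genes adjusted p ran from 1.9e-26 to 0.0030. So 7 of 9 tested members were higher (adjusted over the list alone, 7) and 0 lower, while HLA-DMA (1.10 [SE 0.64]) and HLA-DOB (0.12 [SE 0.25]) did not pass, and the list passed (adjusted p = 7.8e-11, and adjusted p = 0.0018 with an estimated correlation). Read sharing between class II paralogs is not resolved in the table, so the split among HLA-DRB1 and its relatives is uncertain.

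Beyond MHC class II, 2002 genes changed in untreated RREB1 KO, 989 higher and 1013 lower, of which 342 and 42 changed at least 2-fold. JAKMIP2, a microtubule-associated protein, was at least 61.9-fold higher at 13.5 ± 1.68 CPM, and IGLL1, a part of the surrogate light chain of B cell precursors, rose by 4.97 (SE 0.60). EMP1, a membrane protein (-2.15 [SE 0.21]), the gap junction protein GJA1 (-1.91 [SE 0.31]) and the metallothionein MT1H (-1.71 [SE 0.15]) fell. Adjusted p of these 5 ran from 4.5e-18 to 9.9e-07. The leukaemia stem and HOX list rose (adjusted p = 5.9e-06, and adjusted p = 0.0036 with an estimated correlation), with 8 of 10 called (alone, 8), led by HOXA3 (1.98 [SE 0.48]) and HOXA6 (1.92 [SE 0.56]) and with MEIS1, a HOX cofactor, at 0.80 (SE 0.11). The granulocyte list was higher (adjusted p = 0.0138, and adjusted p = 0.178 with an estimated correlation), with 5 of 8 tested members higher and 1 lower (adjusted over the list alone, 5 and 1). MS4A3 (2.74 [SE 0.31]), the antimicrobial peptide CAMP (2.03 [SE 0.60]) and the protease CTSG (0.61 [SE 0.06]) rose and MPO (-0.72 [SE 0.14]) fell. Cell cycle genes were lower (adjusted p = 4.6e-06, and adjusted p = 0.0018 with an estimated correlation), 16 of 27 (alone, 20), by small amounts, as in the replication helicase subunit MCM2 (-0.27 [SE 0.06]).

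Other fixed lists moved less uniformly in untreated RREB1 KO. The IFN-gamma receptor signalling list was lower (adjusted p = 0.0297, and adjusted p = 0.178 with an estimated correlation), with 4 of 14 called (alone, 5), among them the interferon signalling inhibitor USP18 (-0.82 [SE 0.16]) and the phosphatase PTPN6 (-0.23 [SE 0.06]). The lists in the rest of this paragraph did not pass. MHC class I genes had 3 of 21 higher and 6 lower (alone, 5 and 7; list adjusted p = 0.891), with the immunoproteasome subunit PSMB9 at 0.63 (SE 0.13) and B2M, the class I light chain, at -0.27 (SE 0.04). Costimulatory ligands had 2 of 12 higher and 1 lower (alone, 2 and 1; list adjusted p = 0.852), where CD86 fell (-1.23 [SE 0.13]) and NECTIN2 (1.06 [SE 0.13]) and CD70 (0.48 [SE 0.06]) rose. Endolysosomal genes had 2 of 10 higher and 1 lower (alone, 2 and 3; list adjusted p = 0.940), where the proteases CTSH (1.01 [SE 0.19]) and CTSD (0.45 [SE 0.07]) rose and the adaptor subunit AP1S2 (-0.35 [SE 0.08]) fell. Immediate early and heat shock genes had 2 of 9 higher and 5 lower (alone, 2 and 5; list adjusted p = 0.0962), with EGR1 at 1.12 (SE 0.18) and FOS at -0.95 (SE 0.16). RAS-MAPK output genes had 2 of 13 higher and 1 lower (alone, 2 and 2; list adjusted p = 0.831), and the phosphatase DUSP4 had a ratio of 28.3 (4.77 to 1146). Inflammatory genes had 1 of 9 higher and 3 lower (alone, 1 and 3; list adjusted p = 0.0962), and the cytokine IL1B fell (-2.18 [SE 0.51]). MYC and ribosome biogenesis genes had 2 of 20 higher and 2 lower (alone, 2 and 2; list adjusted p = 0.940), and MYC itself fell (-0.51 [SE 0.08]). Integrated stress genes had 2 of 16 higher and 6 lower (alone, 2 and 7; list adjusted p = 0.0890), and the serine synthesis enzyme PSAT1 fell (-0.44 [SE 0.06]). Adjusted p of the genes named here ran from 1.6e-11 to 0.0073.

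With IFN-gamma, FBXO11 KO cells carried more MHC class II transcript than controls. HLA-DRA was 72.4 ± 3.71 against 14.0 ± 2.77 CPM (log2 fold change 2.37 [SE 0.13], adjusted p = 2.9e-25), HLA-DRB1 23.8 ± 4.26 against 4.53 ± 1.20 CPM (2.37 [SE 0.20], adjusted p = 3.0e-16) and CD74 222 ± 24.6 against 129 ± 0.402 CPM (0.78 [SE 0.06], adjusted p = 1.5e-15). In each of these 3 genes all 3 KO libraries lay above all 3 controls. HLA-DPA1 (1.97 [SE 0.52]), HLA-DPB1 (ratio 13.1 [3.27 to 114]) and HLA-DMA, a chain of the peptide-loading catalyst HLA-DM (1.22 [SE 0.34]), also rose, so 6 of 9 members were higher and 0 lower (adjusted over the list alone, 6 and 0). The list passed (adjusted p = 3.7e-09, and adjusted p = 0.0075 with an estimated correlation). CIITA did not differ detectably (2.93 ± 1.93 against 3.15 ± 1.35 CPM, -0.09 [SE 0.38], 95% interval -0.83 to 0.65), nor did HLA-DQB1 (-0.14 [SE 0.70]) or HLA-DOB (0.24 [SE 0.16]). The HLA-DPA1 call was lost without treated FBXO11 KO replicate 2 (1.67, adjusted p = 0.0900) and without treated control replicate 3 (1.68, adjusted p = 0.0665). The HLA-DPB1 call was lost in DESeq2 (adjusted p = 0.0933), without treated control replicate 1 (adjusted p = 0.0643) and without treated control replicate 3 (adjusted p = 0.0581). The HLA-DMA call was lost in DESeq2 (adjusted p = 0.217), without treated FBXO11 KO replicate 1 (1.21, adjusted p = 0.0888), without treated FBXO11 KO replicate 2 (1.17, adjusted p = 0.117), without treated control replicate 1 (1.30, adjusted p = 0.0698) and without treated control replicate 2 (0.97, adjusted p = 0.179).

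Elsewhere, 263 genes changed in treated FBXO11 KO, 126 higher and 137 lower, 33 and 20 of them at least 2-fold. TIMP3 was again near absent in control (ratio 174 [30.8 to 6906]), ENSG00000271043 rose by 3.18 (SE 0.23) and BASP1, a membrane-associated signalling protein, by 1.73 (SE 0.16). CORO2A, an actin-binding coronin (-1.40 [SE 0.21]), complement component C3 (-1.29 [SE 0.26]) and the R-spondin receptor LGR4 (-1.17 [SE 0.27]) fell. The antisense transcript GATA2-AS1 was lower (-1.24 [SE 0.27]), though its reads cannot be told from those of GATA2 where the strand setting is not given. The granulocyte list was lower (adjusted p = 3.0e-04, and adjusted p = 0.0695 with an estimated correlation), with 0 of 8 tested members higher and 4 lower (adjusted over the list alone, 1 and 4). MPO (-0.90 [SE 0.15]), the neutrophil elastase ELANE (-0.46 [SE 0.05]), CSF3R (-0.43 [SE 0.09]) and AZU1 (-0.38 [SE 0.08]) fell. The type I interferon-stimulated list was higher (adjusted p = 0.0212, and adjusted p = 0.176 with an estimated correlation), with 3 of 33 called in edgeR (alone, 3), 6 at an unadjusted p under 0.05 and 0 called in DESeq2. Its IFIT1 (1.00 [SE 0.30]) lost its call in DESeq2 (adjusted p = 0.217), without treated FBXO11 KO replicate 1 (adjusted p = 0.0520), without treated FBXO11 KO replicate 2 (adjusted p = 0.206), without treated FBXO11 KO replicate 3 (adjusted p = 0.0822), without treated control replicate 1 (adjusted p = 0.191), without treated control replicate 2 (adjusted p = 0.105) and without treated control replicate 3 (adjusted p = 0.0677). Of the IFN-gamma response list, 3 of 35 were higher and 1 lower (alone, 3 and 5), and the list did not pass (adjusted p = 0.957). The guanylate-binding protein GBP2 stood at 0.31 (SE 0.05). The member that fell was SERPING1 (-1.07, adjusted p = 0.0042), whose values in the alternatives are not given here. Apart from SERPING1, genes named here without a lost call had adjusted p from 1.2e-20 to 0.0036. DESeq2 called 131 genes, and leaving out treated FBXO11 KO replicate 2 gave 169.

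With IFN-gamma, RREB1 KO cells had the highest class II levels of the 6 groups for HLA-DRA and HLA-DRB1. HLA-DRA was 122 ± 7.80 against 14.0 ± 2.77 CPM in control (log2 fold change 3.12 [SE 0.12]), HLA-DRB1 98.9 ± 2.11 against 4.53 ± 1.20 CPM (4.43 [SE 0.19]) and HLA-DPA1 25.4 ± 2.83 against 0.785 ± 0.406 CPM (4.98 [SE 0.47]). HLA-DPB1 had a ratio of 50.3 (13.6 to 422), HLA-DQB1 rose by 3.30 (SE 0.52), and CD74 was 256 ± 3.43 against 129 ± 0.402 CPM (0.99 [SE 0.06]). Adjusted p of these 6 ran from 1.7e-35 to 5.8e-09. CIITA was 7.14 ± 1.23 against 3.15 ± 1.35 CPM (1.18 [SE 0.33], adjusted p = 0.0079) and HLA-DMA 1.22 (SE 0.34), so 8 of 9 were higher and 0 lower (adjusted over the list alone, 8 and 0) and HLA-DOB (0.12 [SE 0.16]) did not pass. The list passed (adjusted p = 2.3e-13, and adjusted p = 0.0014 with an estimated correlation). The CIITA call was lost in DESeq2 (adjusted p = 0.109), without treated RREB1 KO replicate 1 (1.06, adjusted p = 0.0576) and without treated control replicate 3 (0.96, adjusted p = 0.0687). The HLA-DMA call was lost in DESeq2 (adjusted p = 0.0646), without treated RREB1 KO replicate 2 (1.04, adjusted p = 0.0729) and without treated control replicate 2 (0.97, adjusted p = 0.0781).

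**Figure D2:**
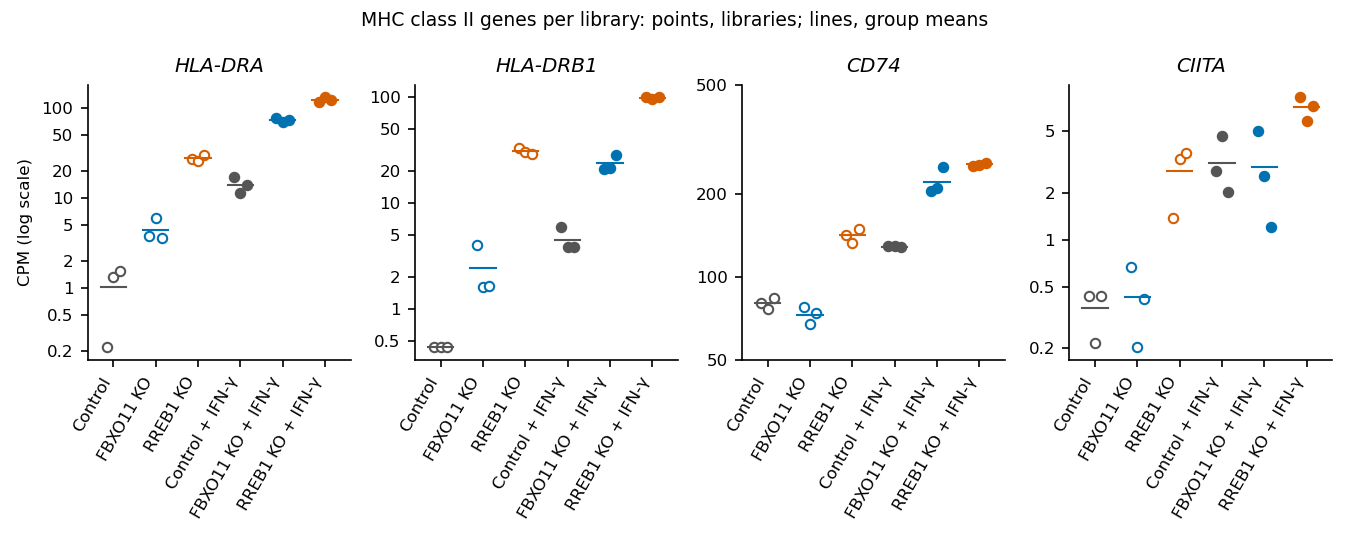
CPM of HLA-DRA, HLA-DRB1, CD74 and CIITA (y axes, log scale) in the 6 groups (x axis), with 1 point per library and a line at each group mean. CD74 in treated FBXO11 KO averages 222 CPM against 129 in treated control, while CIITA averages 2.93 and 3.15.

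In all, 1309 genes changed in treated RREB1 KO, 775 higher and 534 lower, 265 and 39 of them at least 2-fold, and DESeq2 called 840. JAKMIP2 was at least 74.3-fold higher, the neuronal RNA-binding protein ELAVL4 rose by 5.40 (SE 0.61) and CYFIP2, an actin regulator, by 4.33 (SE 0.34). The cytokine IL32 (-1.74 [SE 0.11]), EMP1 (-1.70 [SE 0.25]) and CD101 (-1.27 [SE 0.21]) fell. MTCO2P12 was lower (-2.60 [SE 0.37]), but this mitochondrial pseudogene can take reads of MT-CO2. The granulocyte list was higher (adjusted p = 0.0022, and adjusted p = 0.122 with an estimated correlation), with 5 of 8 tested members higher and 1 lower (adjusted over the list alone, 7 and 1). CAMP (2.14 [SE 0.47]), MS4A3 (1.46 [SE 0.24]) and CTSG (1.03 [SE 0.06]) rose and MPO fell (-0.96 [SE 0.16]). The stem and HOX list was higher (adjusted p = 2.6e-04, and adjusted p = 0.0205 with an estimated correlation), with 4 of 10 called (alone, 5), including HOXA6 (2.42 [SE 0.63]) and GATA2 (0.92 [SE 0.16]). Type I interferon-stimulated genes were higher (adjusted p = 0.0116, and adjusted p = 0.127 with an estimated correlation), 11 of 33 with 1 lower (alone, 13 and 1), as in IFI6 (0.73 [SE 0.08]). Cholesterol synthesis genes were higher (adjusted p = 2.6e-04, and adjusted p = 0.153 with an estimated correlation), 6 of 18 (alone, 7), with the sterol sensor INSIG1 at 0.57 (SE 0.06) and squalene epoxidase SQLE at 0.35 (SE 0.06). The genes of this paragraph had adjusted p from 6.5e-23 to 7.4e-04.

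In treated RREB1 KO 3 further lists passed only with the preset correlation. Oxidative phosphorylation genes were higher (adjusted p = 0.0207, and adjusted p = 0.588 with an estimated correlation), 5 of 26 (alone, 6), with the complex IV subunit COX7B at 0.29 (SE 0.06). The p53 target list was higher (adjusted p = 0.0499, and adjusted p = 0.127 with an estimated correlation), 3 of 20 with 1 lower (alone, 5 and 1), with the cell cycle inhibitor CDKN1A at 0.43 (SE 0.06) and PHLDA3 at 1.03 (SE 0.24). The inflammatory cytokine and NF-kB list was lower (adjusted p = 0.0207, and adjusted p = 0.153 with an estimated correlation), 2 of 9 (alone, 3), with TNF at -0.33 (SE 0.09). The 4 lists that follow did not pass. The IFN-gamma response list had 1 of 35 higher and 5 lower (alone, 3 and 5; list adjusted p = 0.791), with the guanylate-binding protein GBP5 lower (-0.50 [SE 0.06]). Monocyte markers had 1 of 13 higher and 2 lower (alone, 1 and 2; list adjusted p = 0.0575), with TLR2 (-1.13 [SE 0.15]) and lysozyme LYZ (-1.02 [SE 0.24]) lower. Costimulatory ligands had 2 of 12 higher and 2 lower (alone, 3 and 2; list adjusted p = 0.862), with CD86 lower (-0.76 [SE 0.12]) and CD70 higher (0.62 [SE 0.06]). Dendritic cell markers had 2 of 6 higher and 2 lower (alone, 2 and 2; list adjusted p = 0.791), with BATF3 (0.81 [SE 0.15]) and CD83 (0.70 [SE 0.15]) higher and the interleukin 3 receptor chain IL3RA lower (-0.36 [SE 0.09]). Adjusted p of the genes in this paragraph ran from 2.2e-13 to 0.0045.

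IFN-gamma induced its known targets in control, FBXO11 KO and RREB1 KO cells, though not each by the same amount. In control, GBP1, a guanylate-binding GTPase, was at least 305-fold higher, the chemokine CXCL9 at least 26.9-fold higher and the transcription factor ETV7 at least 55.4-fold higher. The immunoproteasome subunit PSMB9 rose by 4.11 (SE 0.11), 3.90 (SE 0.11) and 3.53 (SE 0.09) in control, FBXO11 KO and RREB1 KO. Its smaller rise in RREB1 KO than in control (log2 difference -0.58) passed in the interaction test, a call lost in some fits. Adjusted p of these 4 genes in control ran from 8.8e-46 to 5.9e-11. Of 35 IFN-gamma response genes, 33, 33 and 35 were higher in control, FBXO11 KO and RREB1 KO (adjusted over the list alone, 34, 35 and 35). Of 21 MHC class I genes, 18, 19 and 18 were higher and 2 lower in each (alone, the same counts). Both lists passed in each comparison, the IFN-gamma response list with adjusted p = 2.2e-51, 5.9e-54 and 6.2e-56 and the MHC class I list with adjusted p = 3.3e-26, 1.7e-26 and 5.1e-26. In total 2313, 2235 and 2547 genes changed, of which 1121, 1094 and 1353 were higher.

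MHC class II genes rose with IFN-gamma in each genotype. HLA-DRA rose by 3.75 (SE 0.41) in control, 4.02 (SE 0.20) in FBXO11 KO and 2.15 (SE 0.10) in RREB1 KO, where it started higher. CD74 rose by 0.68 (SE 0.07), 1.60 (SE 0.07) and 0.86 (SE 0.06), CIITA by 3.03 (SE 0.78), 2.73 (SE 0.72) and 1.38 (SE 0.33), and HLA-DOB, a chain of the HLA-DM modulator HLA-DO, by 1.69 (SE 0.22), 2.63 (SE 0.25) and 1.68 (SE 0.20). HLA-DRB1 (3.32 [SE 0.63], 3.30 [SE 0.27] and 1.68 [SE 0.10]) and HLA-DMA (1.97 [SE 0.61], 3.07 [SE 0.55] and 2.09 [SE 0.39]) rose too. HLA-DPA1 rose at least 3.59-fold in control, by 2.62 (SE 0.64) in FBXO11 KO and by 1.85 (SE 0.20) in RREB1 KO. HLA-DPB1 rose in FBXO11 KO (ratio 8.08 [2.48 to 41.7]) and RREB1 KO (2.76 [SE 0.46]) and had 2 counts against 0 in control. HLA-DQB1 did not pass in control (ratio 4.49 [0.957 to 42.1]), FBXO11 KO (ratio 4.19 [0.868 to 39.9]) or RREB1 KO (0.51 [SE 0.28]). For the genes that rose, adjusted p ran from 2.4e-33 to 0.0053. Of 9 tested members, 7, 8 and 8 were higher (adjusted over the list alone, 8, 9 and 8), and the list passed in control (adjusted p = 7.2e-08, and adjusted p = 0.0040 with an estimated correlation), FBXO11 KO (adjusted p = 1.1e-11, and adjusted p = 6.5e-04 with an estimated correlation) and RREB1 KO (adjusted p = 3.2e-08, and adjusted p = 0.0032 with an estimated correlation).

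Other antigen presentation and interferon lists followed. Type I interferon-stimulated genes were higher, 18, 21 and 22 of 33 with 1, 0 and 0 lower (alone, 20, 22 and 26 higher), in control (adjusted p = 4.7e-11, and adjusted p = 5.4e-04 with an estimated correlation), FBXO11 KO (adjusted p = 3.1e-13, and adjusted p = 2.3e-04 with an estimated correlation) and RREB1 KO (adjusted p = 5.6e-22, and adjusted p = 2.2e-05 with an estimated correlation). The IFN-gamma receptor signalling list was higher too (adjusted p = 7.1e-06, and adjusted p = 0.0080 with an estimated correlation in control), with 7, 7 and 8 of 14 called, among them the feedback inhibitor SOCS1 (2.62 [SE 0.23], 2.26 [SE 0.21] and 2.30 [SE 0.18]) and the kinase JAK2 (2.02 [SE 0.13], 1.91 [SE 0.13] and 2.00 [SE 0.13]). Endolysosomal processing genes rose, 6, 6 and 7 of 10 with 1 lower in each (adjusted p = 2.8e-04, and adjusted p = 0.0164 with an estimated correlation in control), as in the cathepsins CTSL (1.00 [SE 0.15] in control) and CTSS (0.92 [SE 0.07]). Costimulation and checkpoint ligands rose, 6, 7 and 7 of 12 with 1 lower in each (adjusted p = 0.0104, and adjusted p = 0.0319 with an estimated correlation in control), as in the poliovirus receptor PVR (0.82 [SE 0.14]) and VSIR (0.85 [SE 0.15]). The monocyte list was higher in control (4 of 13 higher, 2 lower, adjusted p = 0.0488, and adjusted p = 0.263 with an estimated correlation) and FBXO11 KO (6 higher, 1 lower, adjusted p = 0.0255, and adjusted p = 0.186 with an estimated correlation), with lysozyme LYZ at 1.82 (SE 0.29) in control, and did not pass in RREB1 KO (adjusted p = 0.168; difference from control, 0.572). Adjusted p of these 7 genes in control ran from 7.9e-22 to 3.3e-06.

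Falls with IFN-gamma lay in proliferation, immediate early and sterol genes. Cell cycle genes fell in control (21 of 27, adjusted p = 1.6e-10, and adjusted p = 6.3e-05 with an estimated correlation) and FBXO11 KO (22 of 27, adjusted p = 3.0e-11, and adjusted p = 4.6e-05 with an estimated correlation), and in RREB1 KO 10 were lower and 2 higher (adjusted p = 0.0017, and adjusted p = 0.0091 with an estimated correlation). Alone, the counts were 22, 24 and 12 lower. Ribonucleotide reductase RRM2 fell by 0.94, 0.82 and 0.72 on the log2 scale in control, FBXO11 KO and RREB1 KO, and cyclin CCNE2 fell by 1.10, 1.06 and 0.82. The immediate early factor JUN stood at -1.31 (SE 0.12) and -1.44 (SE 0.13) in control and FBXO11 KO, with its list lower in control (5 of 9, adjusted p = 0.0025, and adjusted p = 0.0164 with an estimated correlation) and FBXO11 KO (5 of 9, adjusted p = 7.1e-04, and adjusted p = 0.0099 with an estimated correlation) but not past the test in RREB1 KO (adjusted p = 0.0926; difference from control, 0.215). The RAS-MAPK output list was lower in control (5 of 13, 1 higher, adjusted p = 0.0162, and adjusted p = 0.0394 with an estimated correlation) and FBXO11 KO (3 of 13, adjusted p = 0.0023, and adjusted p = 0.0123 with an estimated correlation) and did not pass in RREB1 KO (adjusted p = 0.145; difference from control, 0.310), with ETV5 at -0.85 (SE 0.08), -0.67 (SE 0.08) and -0.55 (SE 0.08). Cholesterol synthesis genes were lower, 11, 7 and 7 of 18, in control (adjusted p = 2.7e-05, and adjusted p = 0.0669 with an estimated correlation), FBXO11 KO (adjusted p = 3.7e-05, and adjusted p = 0.0716 with an estimated correlation) and RREB1 KO (adjusted p = 0.0020, and adjusted p = 0.197 with an estimated correlation), with HMGCS1 at -0.61 (SE 0.11), -0.52 (SE 0.11) and -0.77 (SE 0.10). Mitochondrially encoded transcripts were lower in control (9 of 15, adjusted p = 0.0026, and adjusted p = 0.480 with an estimated correlation) and RREB1 KO (14 of 15, adjusted p = 2.8e-06, and adjusted p = 0.249 with an estimated correlation) and mixed in FBXO11 KO (3 higher, 3 lower). The lipid droplet protein PLIN2 (-1.82 [SE 0.16]), GJA1 (-3.02 [SE 0.42]) and NREP (-1.74 [SE 0.08]) were among the largest falls in control. The inflammatory list was lower in FBXO11 KO (5 of 9 lower, 1 higher, adjusted p = 0.0255, and adjusted p = 0.135 with an estimated correlation) and did not pass in control (adjusted p = 0.0807; difference, 0.750), with the NF-kB inhibitor NFKBIA at -0.69 (SE 0.08). Adjusted p of the genes named here ran from 2.5e-29 to 1.5e-04.

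The difference between responses to IFN-gamma was tested as an interaction. CD74 rose more in FBXO11 KO than in control, with a log2 difference of 0.92 (SE 0.10) (adjusted p = 2.1e-09), while HLA-DRA (0.27 [SE 0.46]), HLA-DRB1 (-0.02 [SE 0.68]) and CIITA (-0.29 [SE 1.07]) did not differ detectably. MS4A3 rose with IFN-gamma in control and fell in FBXO11 KO (-1.73 [SE 0.22]), a difference of -2.79 (SE 0.41) (adjusted p = 9.3e-06), and its rise in control (1.06 [SE 0.35]) lost its call without untreated control replicate 3 (0.84, adjusted p = 0.109) and without treated control replicate 3 (0.89, adjusted p = 0.0898). Only 9 genes passed, 2 higher and 7 lower, against 706 at an unadjusted p under 0.05. DESeq2 called 4 and a fit without a count filter 21. Counts without untreated FBXO11 KO replicate 2, treated FBXO11 KO replicate 2 and untreated control replicates 1 and 3 were 5, 5, 4 and 5. The MHC class II list was higher (adjusted p = 8.6e-05, and adjusted p = 0.0854 with an estimated correlation), with 1 of 9 called (adjusted over the list alone, 2), and so were mitochondrially encoded transcripts (adjusted p = 9.6e-04, and adjusted p = 0.691 with an estimated correlation), with 0 of 15 called in edgeR (alone, 1), 0 in DESeq2 and 10 at an unadjusted p under 0.05. The list test used log2 CPM with a prior count of 2, which shrinks folds from low untreated levels. In edgeR, CIITA (-0.29), HLA-DQB1 (-0.10) and HLA-DRB1 (-0.02) lay below 0, and HLA-DRA, HLA-DMA, HLA-DOB and CD74 above. HLA-DPA1 and HLA-DPB1 had 0 counts in untreated control, so their differences have no standard error and give no direction. Only CD74 passed, so a larger response of the class II genes as a set is not shown.

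RREB1 KO differed from control in the response of more genes, 312, of which 166 were higher and 146 lower. Tubulin TUBA1A (0.73 [SE 0.08]), the metallothionein MT2A (0.62 [SE 0.08]) and the actin-binding thymosin TMSB10 (0.50 [SE 0.07]) had positive log2 differences, with adjusted p from 1.7e-08 to 4.2e-06. HLA-DRA rose less on the log2 scale, with a difference of -1.60 (SE 0.43) (adjusted p = 0.0066), a call lost without untreated control replicate 1 (-1.13, adjusted p = 0.102). Type I interferon-stimulated genes (adjusted p = 2.7e-04, and adjusted p = 0.0386 with an estimated correlation) responded more, with 1 of 33 called in edgeR, IFIT3 (0.75 [SE 0.17]), 12 at an unadjusted p under 0.05 and 0 called in DESeq2, which gave IFIT3 no adjusted p (unadjusted p = 1.6e-04). Cell cycle genes (adjusted p = 3.3e-04, and adjusted p = 0.0153 with an estimated correlation) had 2 of 27 called (alone, 6), among them MCM2 (0.43 [SE 0.08]). The integrated stress list (adjusted p = 0.0011, and adjusted p = 0.343 with an estimated correlation) had 3 of 16 called (alone, 6), among them PSAT1 (0.55 [SE 0.08]) and the glutathione-degrading enzyme CHAC1 (0.67 [SE 0.13]). Oxidative phosphorylation genes (adjusted p = 2.8e-04, and adjusted p = 0.442 with an estimated correlation) had 3 of 26 called (alone, 5). The called members of the cell cycle, integrated stress and oxidative phosphorylation lists all had positive differences. With IFN-gamma in control, 21 of 27 cell cycle genes were lower, and 6 of 16 integrated stress genes were lower and 1 higher. A positive difference in these lists can therefore be a smaller fall in RREB1 KO. DESeq2 called 227, 176 higher and 51 lower. The count without untreated RREB1 KO replicate 2 was 122, without treated RREB1 KO replicates 2 and 3 it was 174 and 169, without untreated control replicates 2 and 3 it was 170 and 174, and without treated control replicates 1 and 2 it was 167 and 158.

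**Figure D3:**
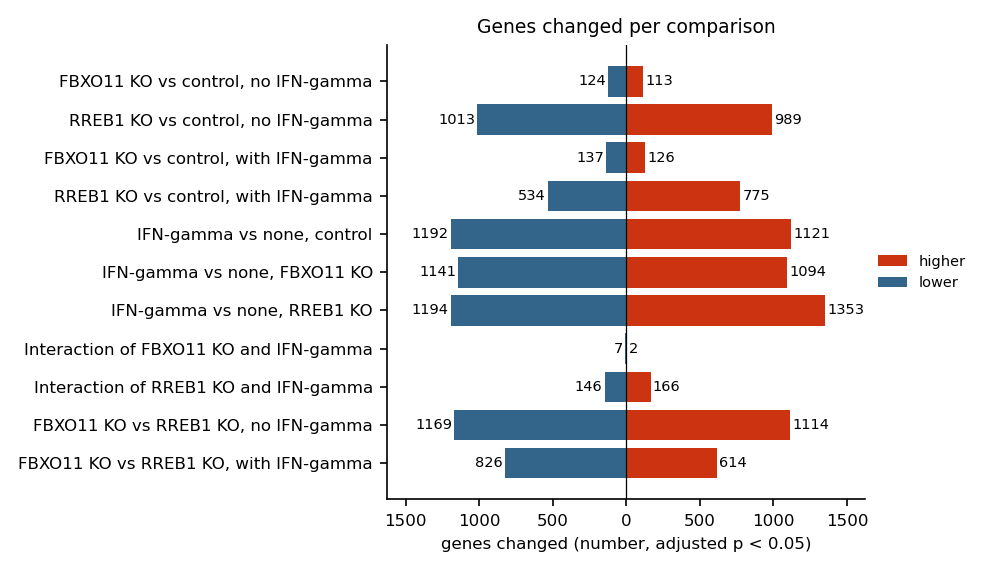
Bars give the number of genes (x axis) higher (right) or lower (left) in each of the 11 comparisons (y axis), counted at adjusted p under 0.05 in edgeR. The interaction of FBXO11 KO and IFN-gamma has 9 such genes and that of RREB1 KO 312.

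The KOs were also compared with each other. Class II levels were lower in FBXO11 KO than in RREB1 KO without IFN-gamma, as in HLA-DRA (-2.62 [SE 0.21]), HLA-DRB1 (-3.67 [SE 0.27]), HLA-DPA1 (-3.77 [SE 0.62]), CD74 (-0.96 [SE 0.07]) and CIITA (-2.63 [SE 0.72]), and HLA-DQB1 had a ratio of 0.0302 (0.00359 to 0.112). With IFN-gamma, HLA-DRA differed by -0.75 (SE 0.08), HLA-DRB1 by -2.06 (SE 0.11), HLA-DPA1 by -3.01 (SE 0.27) and HLA-DQB1 by -3.44 (SE 0.54). In both conditions 7 of 9 members were lower (adjusted over the list alone, 8 and 7) and the list passed (adjusted p = 4.5e-10, and adjusted p = 0.0049 with an estimated correlation untreated, adjusted p = 2.4e-05, and adjusted p = 0.0221 with an estimated correlation treated). The granulocyte list was lower in FBXO11 KO (adjusted p = 2.5e-04, and adjusted p = 0.0415 with an estimated correlation untreated, adjusted p = 3.7e-08, and adjusted p = 0.0104 with an estimated correlation treated), 5 and 7 of 8, with CSF3R at -0.81 (SE 0.09) and -0.65 (SE 0.09). The HOX list was lower too (adjusted p = 1.8e-04, and adjusted p = 0.0109 with an estimated correlation untreated, adjusted p = 5.2e-04, and adjusted p = 0.0221 with an estimated correlation treated), 6 and 3 of 10 (alone, 7 and 6), with GATA2 at -1.26 (SE 0.15) and -1.21 (SE 0.17). Cell cycle genes were higher untreated (adjusted p = 1.0e-03, and adjusted p = 0.0109 with an estimated correlation), 10 of 27 (alone, 12), and the TGF-beta response list was higher treated (adjusted p = 0.0027, and adjusted p = 0.0221 with an estimated correlation), 5 of 11 (alone, 6), with the ligand TGFB1 at 0.52 (SE 0.11). SYT11, a vesicle trafficking protein, differed by -2.50 (SE 0.15) and -2.80 (SE 0.16) and the eosinophil ribonuclease RNASE2 by -0.95 (SE 0.06) and -1.11 (SE 0.06). Adjusted p of the genes named here ran from 7.7e-25 to 4.4e-04. Untreated 2283 genes differed (1114 higher and 1169 lower in FBXO11 KO) and treated 1440 (614 and 826), and DESeq2 called 959 treated.

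Lists that passed between the KOs only with the preset correlation were as follows. Untreated FBXO11 KO was higher in type I interferon-stimulated genes (adjusted p = 0.0316, and adjusted p = 0.225 with an estimated correlation), 6 of 33 with 1 lower, as in USP18 (1.22 [SE 0.15]), and in IFN-gamma receptor signalling (adjusted p = 0.0363, and adjusted p = 0.231 with an estimated correlation), 3 of 14, as in the receptor chain IFNGR2 (0.43 [SE 0.10]). It was lower in mitochondrially encoded transcripts (adjusted p = 2.3e-04, and adjusted p = 0.444 with an estimated correlation), 11 of 15, as in MT-CO3 (-0.53 [SE 0.08]), and in cholesterol synthesis (adjusted p = 0.0379, and adjusted p = 0.444 with an estimated correlation), 6 of 18, as in HMGCS1 (-0.59 [SE 0.09]). Treated FBXO11 KO was lower in cholesterol synthesis (adjusted p = 5.2e-04, and adjusted p = 0.254 with an estimated correlation), 7 of 18, as in INSIG1 (-0.53 [SE 0.06]), and in integrated stress genes (adjusted p = 0.0114, and adjusted p = 0.389 with an estimated correlation), 6 of 16, as in the chaperone HSPA5 (-0.36 [SE 0.05]). Adjusted p of these 6 genes ran from 1.3e-09 to 7.6e-04. Adjusted over the lists alone, the counts in the order given were 6, 3, 13, 7, 7 and 6.

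Genes changed in the same direction by both KOs were counted. Untreated, 47 genes were higher in both, including HLA-DRA, HLA-DRB1, MS4A3, TIMP3 and CKAP4, where independent lists would share 9.86, and 37 were lower in both, where they would share 11.1. In 26 genes the directions were opposite. With IFN-gamma, 53 were higher in both (8.62 if independent), 44 lower (6.46) and 25 opposite, and DESeq2 gave 51 in the same direction. Both KOs were compared with the same 3 controls, which alone makes the fold changes covary. In simulated groups that shared 3 controls and had no true change, the overlap averaged 0.1 genes untreated and 0.08 treated, at most 1, and the log2 fold changes covaried by 0.0202 and 0.0192, against 0.10 and 0.0657 measured. Their correlation was not above that of the simulated groups, at 0.479 and 0.396 measured against means of 0.528 and 0.495 simulated. Few genes can pass in groups without a true change. The simulated overlap therefore does not bound what shared controls add where each KO has many changes of its own, which was not simulated. The simulated libraries also spread only as libraries within a group do. A control culture that departed as a whole was not simulated, so the higher measured covariance cannot be assigned to the KOs. Within FBXO11 KO, 95 genes changed in the same direction with and without IFN-gamma and 0 in opposite directions, and within RREB1 KO 700 and 16. Of the genes changed by IFN-gamma in control, 1478 changed in the same direction in FBXO11 KO and 1285 in RREB1 KO, with 4 and 25 in opposite directions.

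Several fixed lists passed in no comparison. CtBP corepressor genes (21 tested) had 0, 4, 0 and 2 members higher and 0, 3, 0 and 1 lower in untreated FBXO11 KO, untreated RREB1 KO, treated FBXO11 KO and treated RREB1 KO (list adjusted p = 0.550, 0.940, 0.789 and 0.791). The list holds RREB1 itself, which is among the higher members in untreated and treated RREB1 KO. In untreated RREB1 KO the zinc-finger proteins ZMYM2 (0.50 [SE 0.11]) and ZNF217 (-0.45 [SE 0.10]) moved apart, with adjusted p = 3.5e-04 and 4.5e-04. In FBXO11 KO the 0 calls in edgeR stood beside 1 and 3 genes at an unadjusted p under 0.05 and 0 in DESeq2. MHC class II promoter factors such as RFX5 (7 tested) gave 1 call in these 4 comparisons, 1 lower in untreated RREB1 KO, with 2, 3, 0 and 0 at an unadjusted p under 0.05 and 0 in DESeq2 (list adjusted p from 0.138 to 0.991). The SCF-FBXO11 list (12 tested) had 1 lower in FBXO11 KO untreated and treated, FBXO11 itself, and adjusted p = 0.550 and 0.737. In RREB1 KO the SCF-FBXO11 list had 1 higher and 2 lower untreated and 1 higher and 0 lower treated (list adjusted p = 0.258 and 0.560). With IFN-gamma in control it had 3 higher and 4 lower (list adjusted p = 0.819). There its scaffold CUL1 rose (1.27 [SE 0.07]), as did the repressor PRDM1 (2.44 [SE 0.36]), with adjusted p = 4.1e-24 and 4.2e-09. MYC and ribosome biogenesis genes (20 tested) did not pass (adjusted p from 0.101 to 0.940 in KO comparisons), and MYC itself rose with IFN-gamma in control (0.60 [SE 0.08], adjusted p = 1.9e-09).

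Marker lists of other cell types were measured too. Dendritic cell markers (6 tested) and T and NK cell markers (4 tested) did not pass as lists in any comparison. In untreated RREB1 KO dendritic genes had 1 higher and 1 lower (adjusted p = 0.940) and T and NK genes 2 higher (adjusted p = 0.940). With IFN-gamma in control, CD3D, a T cell receptor subunit, fell from 60.8 ± 5.20 to 26.4 ± 0.985 CPM (-1.20 [SE 0.10], adjusted p = 4.1e-16) and CD83, a dendritic maturation marker, fell too (-1.17 [SE 0.15], adjusted p = 1.2e-09). The B cell, epithelial and stromal, and erythroid and megakaryocyte lists had too few tested members for a list test. Of the 8 B cell markers that the count table held, 0 had enough counts to be tested in edgeR. The highest group means of the other lists were PDGFRB at 1.69 CPM in treated RREB1 KO for epithelial and stromal markers, and EPOR at 6.74 CPM in treated control for erythroid and megakaryocyte markers.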

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

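The fits of libraries thinned to 1 total, the fits without the 2 most abundant unnamed IDs and the grouping of splits by their make-up were chosen only after the results were seen, and the other tests in this part before. Every value in the next pair of paragraphs stands here because the response to IFN-gamma differed between a KO and control in a test of that difference (edgeR, adjusted p).

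Against control, 9 genes responded differently in FBXO11 KO. CD74 (0.92 [SE 0.10], adjusted p = 2.1e-09) and MS4A3 (-2.79 [SE 0.41], adjusted p = 9.3e-06) passed in each alternative. The superoxide-producing oxidase subunit CYBB (-0.74 [SE 0.13]) lost its call without untreated FBXO11 KO replicate 2 (-0.63, adjusted p = 0.0965), the neuron navigator NAV3 (-2.46 [SE 0.49]) without untreated control replicate 3 (-2.09, adjusted p = 0.0519), and the translation factor EIF5A (-0.58 [SE 0.11]) in DESeq2 (0.0913), without untreated FBXO11 KO replicate 3 (0.0813), without treated FBXO11 KO replicates 1 (0.0580) and 2 (0.0685), without untreated control replicates 1 (0.0506) and 2 (0.0629), adjusted p in brackets. Of 40 splits of the 12 libraries, 9 gave as many genes, the real one included, and the highest other gave 668, so chance is not excluded for this count. All 8 other splits with as many genes gave the KO label to unequal numbers of FBXO11 KO libraries with and without IFN-gamma, so that the difference between FBXO11 KO and control itself entered the count, a structure of the samples. Of the 19 splits with equal numbers, 0 gave as many genes, but each mixed FBXO11 KO and control libraries in every group. The KO difference then widens the spread within groups and hinders calls, so these splits do not measure chance for the count. Without untreated FBXO11 KO replicate 2, treated FBXO11 KO replicate 2 or untreated control replicates 1 and 3, the count was 5, 5, 4 and 5.

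Against control, 312 genes responded differently in RREB1 KO. Calls that held in each alternative were TUBA1A (0.73 [SE 0.08]), MT2A (0.62 [SE 0.08]), TMSB10 (0.50 [SE 0.07]), PSAT1 (0.55 [SE 0.08]), B2M (0.24 [SE 0.06]), MCM2 (0.43 [SE 0.08]) and CHAC1 (0.67 [SE 0.13]), with adjusted p from 1.7e-08 to 0.0103. ENSG00000272216 (-1.43 [SE 0.22]), IFIT3 (0.75 [SE 0.17]) and the stress factor DDIT3 (0.95 [SE 0.22]) had no adjusted p in DESeq2, whose filter on mean counts left them out (unadjusted p = 1.7e-07, 1.6e-04 and 4.2e-04). Other calls were lost in some fits, given with adjusted p in brackets. HLA-DRA (-1.60 [SE 0.43]) was lost without untreated control replicate 1 (0.102), PSMB9 (-0.58 [SE 0.14]) without untreated RREB1 KO replicate 2 (0.134), without untreated control replicate 3 (0.0602), and the peptide loading factor TAPBP (-0.29 [SE 0.08]) without untreated RREB1 KO replicates 1 (0.0729) and 2 (0.110), without treated RREB1 KO replicate 2 (0.133), without untreated control replicates 1 (0.0823), 2 (0.0592) and 3 (0.0677), without treated control replicate 1 (0.116). DDIT3 was lost without untreated control replicate 2 (0.0533) and the respiratory subunit SDHC (0.50 [SE 0.12]) without treated RREB1 KO replicate 2 (0.0596), without untreated control replicate 3 (0.0667). NDUFA1 (0.31 [SE 0.08]) was lost without untreated RREB1 KO replicate 2 (0.168), without treated RREB1 KO replicates 2 (0.0766) and 3 (0.0549), without untreated control replicates 1 (0.0698) and 3 (0.0710), without treated control replicate 2 (0.0698), and UQCRH (0.24 [SE 0.07]) in thinned libraries (0.0521), without untreated RREB1 KO replicates 1 (0.0752) and 2 (0.111), without treated RREB1 KO replicates 2 (0.0927) and 3 (0.0808), without untreated control replicates 1 (0.0644), 2 (0.0622) and 3 (0.0849), without treated control replicate 2 (0.123). The replication clamp PCNA (0.27 [SE 0.08]) was lost with a stricter count filter (0.0507), without untreated RREB1 KO replicates 1 (0.0803), 2 (0.111) and 3 (0.0534), without treated RREB1 KO replicates 1 (0.0601), 2 (0.0850) and 3 (0.0958), without untreated control replicates 1 (0.0907), 2 (0.0852) and 3 (0.0927), without treated control replicates 1 (0.191) and 2 (0.0622). Of 40 splits, 4 gave as many genes, the real one included, and the highest other gave 1120, so chance is not excluded for this count either. The 3 others with as many genes also had unequal numbers of RREB1 KO libraries under the KO label, and of the 18 splits with equal numbers 0 gave as many. Those 18 mixed RREB1 KO and control libraries in every group, so they do not measure chance for the count either. Without untreated RREB1 KO replicate 2 the count was 122, without treated RREB1 KO replicates 2 and 3 174 and 169, without untreated control replicates 2 and 3 170 and 174, and without treated control replicates 1 and 2 167 and 158.

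The larger CD74 response in FBXO11 KO was weighed against technical explanations. CD74 rose from 73.0 ± 5.16 to 222 ± 24.6 CPM in FBXO11 KO and from 80.5 ± 3.67 to 129 ± 0.402 CPM in control. Leaving out any 1 of the 12 libraries gave differences of 0.83 to 0.98 with adjusted p up to 1.7e-07, which argues against 1 library as the source. Thinning the libraries to 1 total gave 0.94 (adjusted p = 2.0e-09), and DESeq2 gave 0.92. The 12 libraries already held similar totals, 4654123 to 5290947 counts, so thinning removed few reads and is a weak test of depth. An effect of FBXO11 on the CD74 response may underlie it and was not tested apart from the culture, since the labels name no second guide or clone per genotype.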

How the results depend on the processing

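The fit without the 2 most abundant unnamed IDs and the fit of thinned libraries were chosen only after the results were seen. Of 222 counts that answer a comparison under an alternative, 192 were within 1.5 times the value reported. DESeq2 called fewer genes: 135 (FBXO11 KO untreated), 131 (FBXO11 KO treated), 840 (RREB1 KO treated), 4 (FBXO11 KO interaction), 959 (KO against KO, treated) and 51 shared by both KOs with IFN-gamma. The FBXO11 KO interaction without a count filter gave 21, and a fit of only the groups compared gave 373 for untreated FBXO11 KO. With an estimated correlation, the number of called lists went from 2 to 0 in untreated FBXO11 KO, 5 to 3 in untreated RREB1 KO, 3 to 1 in treated FBXO11 KO, 8 to 2 in treated RREB1 KO, 2 to 0 and 4 to 2 in the FBXO11 KO and RREB1 KO interactions, and 8 to 4 between untreated KOs. Leaving out 1 library gave 141 to 201 genes in untreated FBXO11 KO, 169 to 227 in treated FBXO11 KO, 4 to 11 in the FBXO11 KO interaction and 122 to 389 in the RREB1 KO interaction. The replicate block gave 300.0 and 2117 genes for untreated FBXO11 KO and RREB1 KO and moved no count by more than 1.5 times. Among the list tests, it gave adjusted p = 0.0739 against 0.0499 for p53 targets in treated RREB1 KO, 0.0644 against 0.0488 for monocyte markers with IFN-gamma in control, and 0.0461 against 0.0926 for immediate early genes with IFN-gamma in RREB1 KO, so 2 calls ended and 1 was added, and it changed no other list call. Thinned libraries gave 223 and 1874 genes for untreated FBXO11 KO and RREB1 KO, and the fit without the abundant IDs 240.0 and 2004. The cause of these differences was not tested.

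Among named genes, no called gene changed direction in any alternative. Of 732 calls, 201 were lost in some fit that left out a library and 27 without a count filter, and of the calls tested in the other fits 131 of 727 were lost in DESeq2, 39 of 731 in thinned libraries and 22 of 702 in a fit of only the groups compared. The direction of uncalled genes turned as follows, and the cause was not tested. Thinning gave 0.0016 for HLA-DQB1 in untreated FBXO11 KO, -0.14 for HLA-DPB1 in the RREB1 KO interaction and 0.012 for HLA-DMA between treated KOs. The fit without a count filter gave 0.00042 for that gene and 0.0095 for HLA-DOB in the RREB1 KO interaction, which was 0.0011 without the abundant IDs. Leaving out 1 library gave log2 values in untreated FBXO11 KO of -0.55 to 0.48 (HLA-DQB1), -0.48 to 0.53 (HLA-DMA) and -0.22 to 0.54 (CIITA), and in treated FBXO11 KO of -1.10 to 0.28 (HLA-DQB1) and -0.72 to 0.29 (CIITA). HLA-DOB ran from -0.018 to 0.30 in untreated and -0.015 to 0.20 in treated RREB1 KO. For IFN-gamma against none, RREB1 ran from -0.092 to 0.028 within FBXO11 KO cells and FBXO11 from -0.13 to 0.016 within RREB1 KO cells. In the FBXO11 KO interaction the ranges were -0.14 to 0.74 (HLA-DRA), -0.24 to 0.52 (HLA-DRB1), -0.35 to 3.48 (HLA-DPB1), -1.06 to 0.41 (HLA-DQB1) and -0.93 to 0.13 (CIITA). In the RREB1 KO interaction they were -0.040 to 0.10 (FBXO11), -0.44 to 2.76 (HLA-DPB1), -0.27 to 0.35 (HLA-DMA) and -0.18 to 0.13 (HLA-DOB), and between treated KOs -0.23 to 0.18 (HLA-DMA). Depth limits what can be said of class II genes with few counts: HLA-DQA1 had 0 to 9 and HLA-DMB 1 to 34 counts over a group. HLA-DPB1 had 0 in untreated control, so its interaction values give no direction.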

Other observations

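The tests of mixed cultures, of a hidden CIITA rise and of 1 source of other cells were chosen only after the results were seen. The splits and the count of genes absent in 1 genotype were chosen before.

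MHC class II genes were higher in treated FBXO11 KO than in treated control while CIITA did not differ detectably, with an upper 95% bound of its log2 fold change of 0.65 against 1.18 in RREB1 KO, which argues against a CIITA rise as large as there and leaves a smaller one open. Without treated FBXO11 KO replicates 1 and 3 the bound was 0.18 and 1.03, and without treated control replicate 2 it was 1.16, where RREB1 KO stood at 1.56, while the difference between the KOs (-1.27 [SE 0.34], adjusted p = 0.0039) kept an upper 95% bound under 0 in each fit that held it but lost its call in DESeq2 (adjusted p = 0.0612) and without treated FBXO11 KO replicate 3 (-0.91, adjusted p = 0.0674). Mixed-in RREB1 KO cells would bring the same share of each RREB1 KO rise. Over 39 other genes at least 8-fold higher in RREB1 KO, the first quartile of the shares was 2.17%, the median 13.4% and the third quartile 42.6%. The abundant RREB1 KO transcripts JAKMIP2, ELAVL4 and CYFIP2 showed shares of 0.89%, 1.97% and 2.37%. These low shares argue against mixing as the whole cause for HLA-DRB1 (20.4%), HLA-DRA (54.0%) and CD74 (72.8%). HLA-DRA, CD74 and HLA-DMA (98.3%) also lay above the third quartile, but that split was drawn after the first comparison and adds no support. By the rule set for this test, mixing was kept if the median share reached the lowest class II share. It did, since HLA-DPA1 showed 9.58%. HLA-DPA1, HLA-DPB1 (24.4%) and HLA-DMA also lay above the shares of JAKMIP2, ELAVL4 and CYFIP2. The calls of these class II genes were lost in some fits, so mixing is left open for them without a verdict. An effect of the FBXO11 KO that does not pass through CIITA transcript level may also hold and was not tested.

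A few genes were near absent in control (under 0.2 CPM) and present (at least 1 CPM) in both KOs, with and without IFN-gamma. They were TIMP3, CKAP4 and, chosen after their values were seen, the homeobox genes UNCX and LHX2. A control culture that departed from the others would leave more genes absent in control alone than in either KO alone, and the counts were 4 in control, 0 in FBXO11 KO and 0 in RREB1 KO, which restates the pattern and would follow from a shared effect of the KOs too, so the pair cannot be told apart. A single source of other cells in both KO cultures would give 1 ratio of RREB1 KO to FBXO11 KO levels. The untreated ratios ran from 0.24 (TIMP3) to 0.42 (LHX2), 1.73 times apart. The counting intervals of TIMP3 (0.190 to 0.301) and CKAP4 (0.304 to 0.437) did not meet, and those of other pairs did. These intervals leave out the spread between libraries, so with 4 genes a single source cannot be told apart from a shared effect of the KOs. A shared biological effect was not tested.

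For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Each split other than the real one mixes libraries of both groups, which widens the spread within groups and hinders calls. The highest counts of the others were 1 against 237 (untreated FBXO11 KO), 1 against 2002 (untreated RREB1 KO), 9 against 263 (treated FBXO11 KO), 1 against 1309 (treated RREB1 KO), 0 against 2313, 2235 and 2547 (IFN-gamma in control, FBXO11 KO and RREB1 KO), 1 against 2283 (KO against KO untreated) and 0 against 1440 (treated).

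Among values outside the comparisons, the total counts of HLA-DMB were 34 in treated FBXO11 KO, 10 in treated RREB1 KO and 7 in treated control. The gene did not pass the count filter of the main fit, so no test of it is given.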
